A study of Mus musculus with 10 samples.

How the data were processed

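The data are raw counts of RNA-seq reads per gene in biceps femoris muscle of 10 mice. Per the submitters' processing notes the tools were TopHat2 2.1, Bowtie2 2.2.6, SAMtools 1.2, HTSeq 0.6.1 and DESeq2 1.10, with the mouse genome build GRCm38. Counting settings, strand and the gene model release are not given in the sources used here, so reads of overlapping or antisense genes cannot be told apart; 18 of the 96 named genes overlap another tested gene. Near-identical copies, as among the Cyp4a, globin, major urinary protein and MHC genes, share reads in an unknown way. The deposited table holds whole-number counts, not normalized, for 5 wild-type and 5 transgenic libraries. The same table holds the authors' mean signal per gene over the libraries, their log2 fold change, its standard error, the Wald statistic (a score) and the authors' p-values. The deposited mean signal was checked against the counts: the ratio of recomputed to deposited means ran from 0.979 to 1.01. The adjusted p-values of the authors' deposited table correspond to about 18268 genes tested, while 15883 rows were used here, so that table is held in part. Of the gene names, 23 had been turned into dates, and no name was changed here.

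Libraries were grouped by the column names, which match the labels' groups but not single mice. The series describes separate mice. Genes were filtered with filterByExpr, scaled by TMM and tested with edgeR 4.0.16 (glmQLFit and glmQLFTest) in R 4.3.3, transgenic against wild type with no covariate, with Benjamini-Hochberg adjustment over 13338 genes. Standard errors of log2 fold changes were taken from the fold change and the F statistic. CPM values are TMM-scaled, and log2 CPM used a prior count of 2. Gene lists were tested with camera in limma 3.58.1 with an inter-gene correlation preset at 0.01 and adjusted over 33 lists. Coordinates come from GENCODE release M21 on GRCm38, matched by gene ID for 99.8% of genes tested.

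The tests, the 33 lists and the rule for naming genes were fixed before the data were examined. The rule names Zfp407, the 10 largest rises and 10 largest falls among genes past an adjusted p of 0.05 with a mean normalized count of at least 20, up to 3 called members of each list or up to 2 members with the smallest p where none passed, and a panel of 12 metabolic genes; some genes it takes are not reported here. Lists of hepatocyte markers, antigen presentation genes and imprinted genes were added after called genes had been seen. The alternatives were other size factors, DESeq2 1.42.0, other filters and thresholds, the authors' p-values, each library left out, other settings of camera, and settings added later that concern prior counts, liver and leukocyte transcripts, rows that resemble ribosomal RNA and gene types.

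Counts were simulated for 13338 independent genes with the real means and library sizes and a dispersion set by mean level alone. On these, edgeR recovered 28% of genes changed 1.5-fold, 74% at 2-fold, 98% at 4-fold and 100% at 8-fold, with 5 false calls. Genes that vary more than others of their level, or that vary together, are not covered. Depth ran from 13530367 to 19047834 counts per library. The rows Lars2, Gm15564 and Gm15662 took 9.62% to 33.9% of the counts per library, with a mean of 23.1% in wild type and 14.2% in the transgenic group. No 2 libraries of a group agreed within sampling noise, with a chi-square per degree of freedom of at least 17.5 in each of 20 pairs.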

Results

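RNA was sequenced from the biceps femoris, a hindlimb muscle, of 10 male C57BL/6J mice aged 5 weeks and fasted for 16 hours. The series names 5 mice of wild type and 5 mice that carry a Zfp407 transgene. Zfp407 encodes a zinc finger protein. The count table holds 15883 genes and 10 libraries. Total counts ran from 13530367 to 17814900 per library in wild type and from 15162400 to 19047834 in the transgenic group. The columns name the group of each library but not the mouse, so libraries are called by group and column number. Levels are given as CPM, the count of a gene scaled to the TMM-adjusted total of its library. The comparison asks which transcripts differ in muscle when Zfp407 is overexpressed, and the title of the series ties this to glucose homeostasis.

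Zfp407 rose in the transgenic group. Its level was 22.9 ± 1.73 CPM (SD, n = 5) in wild type and 489 ± 124 CPM (SD, n = 5) in the transgenic group. The log2 fold change was 4.41 ± 0.19 (SE; edgeR adjusted p = 8.15e-08), a fold of 21.3. Every transgenic library, from 317 to 616 CPM, lay above every wild-type library, from 21.0 to 25.7 CPM. An exact two-sided permutation test over the 252 ways to split the libraries gave p = 0.00794, the smallest it can give. The gene lies on chromosome 18 from 84128027 to 84589725 (GRCm38), and counts per gene do not separate the transgene from the endogenous copy.

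**Figure D1:**
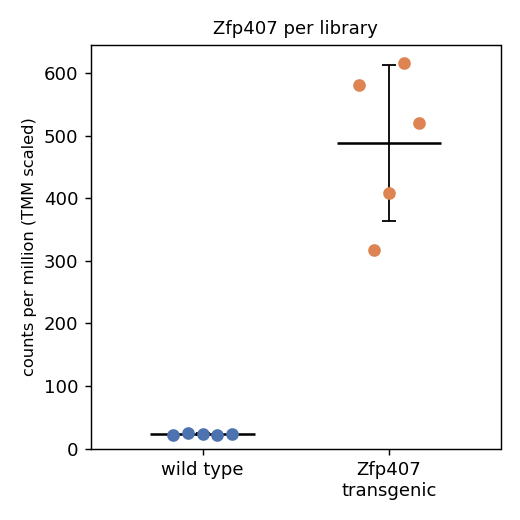
Zfp407 in TMM-scaled CPM (vertical axis) in the 5 wild-type and 5 transgenic libraries; points are libraries, lines are group means and bars are 1 SD. The transgenic libraries lie between 317 and 616 CPM and the wild-type libraries between 21.0 and 25.7 CPM.

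Many genes changed beside Zfp407, mostly upward. Of 13338 genes tested with edgeR's quasi-likelihood test, 711 passed an adjusted p of 0.05, of which 571 were higher and 140 lower in the transgenic group. Of the called genes, 377 rose and 26 fell by at least 2-fold. The libraries of the groups did not overlap in 1073 of the 13338 genes tested, where chance gives 0.794% of genes. Of these, 637 were called genes, and in called genes such separation follows largely from the call. The median log2 fold change of all genes tested was 0.003. The count fell to 450 without wild-type library 3 and rose to 1116 without transgenic library 3. The authors' deposited table calls 1158 genes, 876 higher and 282 lower.

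Among the 10 largest rises were Dll1, a ligand of Notch receptors, Susd4, Hap1, St14, a membrane serine protease, Tex16 and Rgn. Dll1 rose from 3.35 ± 0.834 CPM to 72.04 ± 23.7 CPM (SD, n = 5 each), with a log2 fold change of 4.41 ± 0.28 (SE; edgeR adjusted p = 2.90e-06). Susd4 rose by a log2 fold change of 4.53 ± 0.30, Hap1 by 4.47 ± 0.36, St14 by 5.03 ± 0.47 and Rgn by 5.15 ± 0.39 (SE). Tex16 had 3 counts over the wild-type libraries and 230 over the transgenic libraries, a ratio of 59.8 with a 95% exact interval of 20.2 to 292 that covers counting error only. The other rises in this set were Zfp407 itself, Ces3b, Apon and F13b. The log2 fold changes of the last 3 were 4.30, 4.29 and 4.22, and 2.96, 2.93 and 3.26 without transgenic library 5. Ces3b had 0.195 ± 0.161 CPM in wild type and 4.05 ± 5.65 CPM in the transgenic group (SD, n = 5 each), where the SD exceeds the mean, and lost its call without wild-type library 2, 3 or 4 (edgeR adjusted p from 0.0511 to 0.0592).

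Among the 10 largest falls were Stxbp4, Ndufa1, Plin3 and Cdkn1c. Ndufa1, a subunit of respiratory complex I, fell from 41.5 ± 4.73 CPM to 10.6 ± 1.59 CPM (SD, n = 5 each; log2 fold change -1.97 ± 0.13, SE; edgeR adjusted p = 3.72e-06). Plin3, a lipid droplet coat protein, went from 30.6 ± 3.58 CPM to 9.84 ± 1.96 CPM (SD, n = 5 each). Stxbp4 had a log2 fold change of -2.22 ± 0.28 (SE), and Cdkn1c, an imprinted inhibitor of the cell cycle, one of -1.42 ± 0.21 (SE). Abca4, Nek3, Lrp2bp, Calr3, Hsbp1l1 and Casr complete the set, with log2 fold changes from -1.81 to -1.39. Casr lost its call without wild-type library 1, 4 or 5 or any 1 of transgenic libraries 1 to 5, with an edgeR adjusted p from 0.0633 to 0.110.

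Transcripts of the liver were higher in the transgenic libraries. Alb, the serum albumin gene, stood at 66.9 ± 30.8 CPM in wild type and 924 ± 1199 CPM in the transgenic group (SD, n = 5 each). Transgenic library 5 held 3038 CPM and the other transgenic libraries 197 to 715 CPM, with a mean of 395 CPM. Of 41 hepatocyte markers tested, a list written after called genes had been seen, 39 rose, and 40 when adjusted over the list alone, with a median log2 fold change of 3.52, and 22 rose without wild-type library 3. The median was 2.37 without transgenic library 5 and 1.95 without transgenic libraries 4 and 5. The camera test over the 3 lists added later gave adjusted p = 1.26e-30 with a preset correlation and adjusted p = 0.0788 with an estimated correlation, which was 0.0344 without transgenic library 5. As the hepatocyte list was written after called genes had been seen, these p-values describe it and do not test it. Together these markers gave 0.0220% to 0.0325% of the counts in wild-type libraries and 0.0729% to 0.807% in transgenic libraries, the highest in transgenic library 5. With the mean of these markers as a covariate 79 genes passed, and 64 of the 711 genes kept their call. Zfp407, Dll1, Susd4, Hap1, St14, Tex16, Rgn, Ndufa1 and Plin3 stayed past the threshold in that fit. Ces3b, Apon and F13b did not, with log2 fold changes of 0.42 ± 0.51, 0.44 ± 0.48 and 1.22 ± 0.56 (SE) beside the covariate. The falls of Stxbp4, Abca4, Nek3, Lrp2bp, Calr3, Hsbp1l1, Cdkn1c and Casr did not pass in it either. Their log2 fold changes there ran from -2.29 to -0.99 and the edgeR adjusted p from 0.0650 to 0.270, with a larger SE for each. Stxbp4 went from -2.22 ± 0.28 to -2.29 ± 0.51 and Calr3 from -1.64 ± 0.23 to -1.66 ± 0.45 (SE). Nek3 shrank from -1.76 to -1.07 and Cdkn1c from -1.42 to -0.99. The covariate separates the groups, so a call lost beside it does not show that liver transcripts made the change.

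Of 21 interferon-stimulated genes measured, 17 rose and none fell, and 20 rose when adjusted over the list alone; the median log2 fold change was 0.97. The camera test gave adjusted p = 2.61e-19 for the list with a preset correlation and adjusted p = 0.0981 with an estimated correlation. Without wild-type library 1 the members that rose were 10, and without wild-type library 2 or 3 they were 11. Irf7, a transcription factor of the interferon response, rose from 3.31 ± 0.756 CPM to 11.1 ± 3.29 CPM (SD, n = 5 each; edgeR adjusted p = 0.000562). Oasl2 and Ifit1 each rose by a log2 fold change of 1.42, with SE of 0.17 and 0.21. Irf7 overlaps Phrf1 on the opposite strand. With the hepatocyte markers as a covariate 1 member passed, Irf7 (edgeR adjusted p = 0.0481), and the median was 0.67. Oasl2 had a log2 fold change of 1.05 ± 0.25 and Ifit1 one of 1.44 ± 0.35 in that fit (SE, edgeR adjusted p = 0.0885 and 0.0891). Both thus kept most of their change while the SE grew. Hepatocyte markers were higher in the same libraries.

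Leukocyte markers were the other list past the threshold, with a camera adjusted p = 0.00641 with a preset correlation and adjusted p = 0.975 with an estimated correlation. Of 18 members tested, 3 rose, all of them genes of the antigen presentation pathway of MHC class II, and 4 rose when adjusted over the list alone. Cd74 had 36.3 ± 6.68 CPM in wild type and 67.3 ± 21.0 CPM in the transgenic group (SD, n = 5 each), H2-Aa a log2 fold change of 0.93 ± 0.23 and H2-Ab1 one of 0.84 ± 0.18 (SE). Ptprc, the pan-leukocyte gene, stood at 41.9 and 60.5 CPM in transgenic libraries 1 and 2 and at 7.34 to 16.6 CPM in the other transgenic libraries. Without transgenic libraries 1 and 2, or without wild-type library 3, no member of the list passed, and without the pair the camera adjusted p was 0.545. With the hepatocyte markers as a covariate 4 members rose, Cd74, H2-Aa, H2-Ab1 and Tyrobp, with a list median log2 fold change of 1.26 against 0.41 and a camera adjusted p = 2.26e-12 with a preset and adjusted p = 0.574 with an estimated correlation. Without transgenic libraries 4 and 5, 5 members rose, with a camera adjusted p = 7.57e-07 with a preset and adjusted p = 0.9998 with an estimated correlation. Cd74 and H2-Aa lost their calls without wild-type library 1, 3, 4 or 5 or transgenic library 1 or 2, with an edgeR adjusted p from 0.0513 to 0.0726 and from 0.0564 to 0.0855, and H2-Ab1 had one of 0.0516 without wild-type library 3. The list also lost its call without wild-type library 4 or 5 or transgenic library 1 or 2, with adjusted p from 0.0635 to 0.0920.

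**Figure D2:**
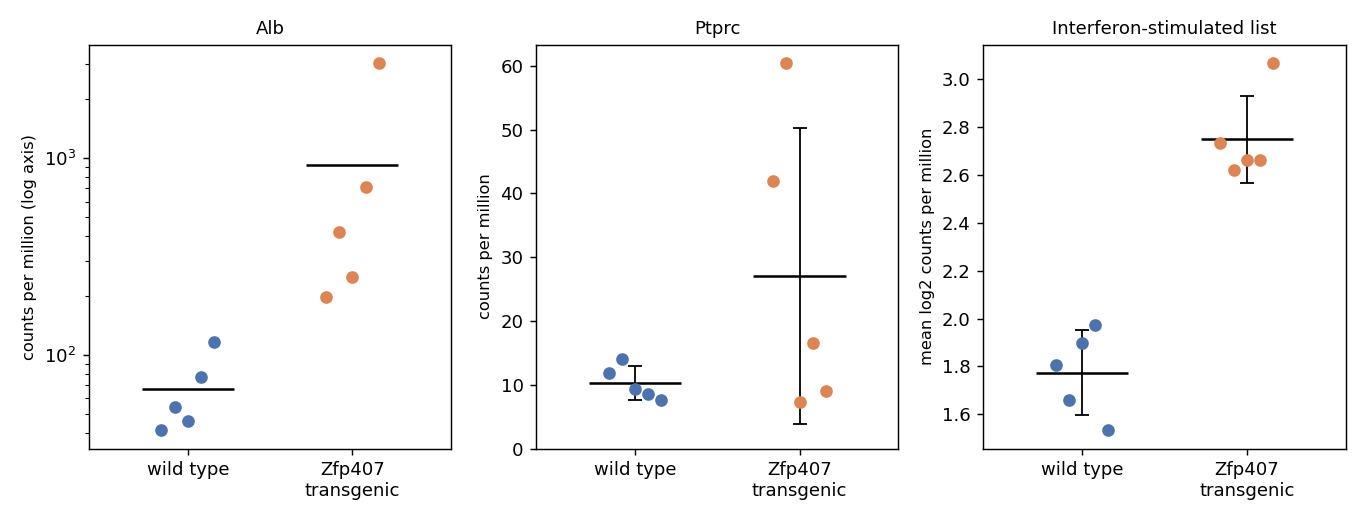
Alb (left, CPM on a log axis), Ptprc (middle, CPM) and the mean log2 CPM of the interferon-stimulated list (right) in each library; points are libraries, lines are group means and bars, in the middle and right panels, are 1 SD. Alb and the interferon list are higher in each transgenic library than in each wild-type library, while Ptprc is high in transgenic libraries 1 and 2 alone.

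The PPAR target list did not pass as a group. Of 44 members measured 6 rose and none fell, and 8 rose and 2 fell when adjusted over the list alone; the camera adjusted p was 0.722. The members that rose were 3 without wild-type library 1 or 4 and 2 without wild-type library 3, and 3 members fell without transgenic library 3. Cyp4a10 rose by a log2 fold change of 3.81 ± 0.76, Cyp4a14 by 3.70 ± 0.76 and Plin2, a lipid droplet protein, by 0.79 ± 0.17 (SE; edgeR adjusted p = 0.0108, 0.0128 and 0.0137). Acaa1b, at 2.71, and Ehhadh, at 1.84, are among the other members that rose. Without transgenic library 5 the log2 fold change was 2.57 for Cyp4a10, 2.33 for Cyp4a14, 1.64 for Acaa1b and 1.15 for Ehhadh. By edgeR adjusted p, Acaa1b lost its call without any 1 of wild-type libraries 1 to 5 or transgenic library 4 (0.0654 to 0.108), Ehhadh without wild-type library 1, 3, 4 or 5 (0.0516 to 0.0595) and Plin2 without wild-type library 3 (0.0507). None of the 6 passed with the hepatocyte markers as a covariate, where the log2 fold change was 0.14 ± 0.26 for Cyp4a10, -0.15 ± 0.22 for Cyp4a14, -0.32 ± 0.56 for Acaa1b, 0.11 ± 0.35 for Ehhadh and 0.90 ± 0.28 for Plin2 (SE). Pdk4, a kinase that restrains pyruvate dehydrogenase, had 2885 ± 301 CPM in wild type and 2402 ± 333 CPM in the transgenic group (SD, n = 5 each; edgeR adjusted p = 0.322). Cpt1b, Angptl4, Ucp3, Ppargc1a, Ppara, Ppard and Pparg did not pass either, with log2 fold changes from -0.24 to 0.54. The fatty acid beta-oxidation list (22 genes) and the list of mitochondrial and PPAR regulators (22 genes) had no member past the threshold.

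Genes of glucose uptake moved singly. Slc2a4, which encodes the insulin-responsive glucose transporter GLUT4, stood at 214 ± 22.4 CPM in wild type and 253 ± 71.1 CPM in the transgenic group (SD, n = 5 each; edgeR adjusted p = 0.496). Transgenic library 3 stood apart, with a log2 CPM of 8.56 for Slc2a4 against 7.69 to 7.89 in the other transgenic libraries. Of 43 genes of insulin signalling and glucose uptake, Tbc1d1 rose by a log2 fold change of 1.27 ± 0.26 and Tbc1d4 fell, at -0.42 ± 0.11 (SE; edgeR adjusted p = 0.0120 and 0.0325), and the same 1 and 1 passed when adjusted over the list alone. Both encode GTPase-activating proteins of glucose transporter traffic. Tbc1d4 lost its call without any 1 of wild-type libraries 1 to 5 or transgenic library 2, 4 or 5, with an edgeR adjusted p from 0.05005 to 0.0938. Tbc1d1 overlaps the antisense gene Gm15824. Insr, Irs1 and Hk2 did not pass, with log2 fold changes from -0.17 to 0.10. In glycolysis and glycogen, Slc16a1 and Fbp2 each rose by 0.62 and the other 31 genes did not pass. Pcx, at 0.80 ± 0.20, rose and Pdha1, at -0.42 ± 0.11 (SE), fell among 28 genes of pyruvate dehydrogenase and the TCA cycle. By edgeR adjusted p, Slc16a1 lost its call without wild-type library 2, 3, 4 or 5 or transgenic library 5 (0.0542 to 0.0863), Fbp2 without wild-type library 1, 2, 3 or 4 or transgenic library 1, 3, 4 or 5 (0.0599 to 0.132), Pcx without wild-type library 1, 2, 3 or 4 or transgenic library 4 or 5 (0.0615 to 0.118) and Pdha1 without wild-type library 1, 4 or 5 or transgenic library 1, 2, 4 or 5 (0.0633 to 0.0833). None of these 6 genes passed with the hepatocyte markers as a covariate. There Tbc1d1 had a log2 fold change of 1.11 ± 0.42 and Tbc1d4 one of -0.16 ± 0.17 (SE, edgeR adjusted p = 0.307 and 0.702). Slc16a1 stood at 0.47 ± 0.24, Fbp2 at 0.59 ± 0.28, Pcx at 0.82 ± 0.34 and Pdha1 at -0.56 ± 0.19 (SE). Their edgeR adjusted p was 0.445, 0.400, 0.344 and 0.249 in that order. Except for Tbc1d4 these genes kept most of their change while each SE grew. Their lost calls thus do not show that liver transcripts made the changes.

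Other metabolic lists held few calls. Of 72 nuclear-encoded respiratory chain genes Ndufa1, Ndufa13 and Atp5l fell and none rose, and none of 11 mitochondrially encoded genes passed. Without transgenic library 3, 5 respiratory chain genes fell, and 1 rose without transgenic library 1. Ndufa1 alone of the list passed without transgenic libraries 1 and 2, without transgenic libraries 4 and 5 or beside the hepatocyte covariate. With that covariate Ndufa13 had a log2 fold change of -0.44 ± 0.21, against -0.61 ± 0.12 without it (SE, edgeR adjusted p = 0.420). Atp5l had one of -0.49 ± 0.20, against -0.49 ± 0.11 (SE, edgeR adjusted p = 0.343), so for Atp5l the SE alone grew. Fads1 rose by 1.43 ± 0.17 (SE) among 20 genes of fatty acid and triglyceride synthesis. Of 18 genes of cholesterol synthesis 2 rose and none fell, and 1 rose without wild-type library 1, 2, 3 or 4 or transgenic library 3, 4 or 5. Psmd12, at -0.85 ± 0.11, and Psma6, at -0.47 ± 0.10 (SE), fell among 30 proteasome genes. Gpx1 rose among 17 antioxidant genes, Sdf2l1 among 20 genes of the unfolded protein and integrated stress response, Ciart among 19 clock genes and Mcm6 among 15 cell cycle genes. By edgeR adjusted p, Ciart lost its call without wild-type library 2, 3, 4 or 5 or transgenic library 5 (0.0636 to 0.0934), Mcm6 without wild-type library 2, 3, 4 or 5 or transgenic library 2 (0.0513 to 0.0784) and Psma6 without transgenic library 4 (0.0502). The genes that fell in the proteasome list were 3 without transgenic library 3, and those that rose were 2 among antioxidant genes without wild-type library 2 and 2 in fatty acid and triglyceride synthesis without transgenic library 4. With the hepatocyte markers as a covariate Sdf2l1 passed (edgeR adjusted p = 0.0209). Fads1, Psmd12, Psma6, Gpx1, Ciart and Mcm6 did not, with an edgeR adjusted p from 0.0651 to 0.443 and a larger SE for each. Their log2 fold changes there were 1.18, -0.87, -0.35, 0.92, 0.75 and 1.22, against 1.43, -0.85, -0.47, 0.82, 0.86 and 0.77 without it. These lost calls do not show that liver transcripts made the changes.

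Markers of muscle stem cells rose in part. Myf5 and Pax7, transcription factors of satellite cells, rose among 17 genes of satellite cells, regeneration and denervation. Myf5 went from 2.24 ± 0.520 CPM to 7.29 ± 1.96 CPM (SD, n = 5 each; edgeR adjusted p = 0.000940) and Pax7 had a log2 fold change of 0.93 ± 0.18 (SE; edgeR adjusted p = 0.00969). Beside the hepatocyte markers as a covariate Myf5 had a log2 fold change of 1.29 ± 0.35 and Pax7 one of 0.71 ± 0.30 (SE; edgeR adjusted p = 0.140 and 0.363), and without transgenic libraries 4 and 5 Pax7 had an adjusted p of 0.0568. No member passed in the lists of slow fibre, fast fibre, atrophy and autophagy, glucocorticoid-responsive, heat shock, immediate early, cytosolic ribosomal protein and muscle-secreted genes. None passed among the markers of adipocytes, endothelium, pericytes and smooth muscle, fibroblasts and extracellular matrix, tendon, nerve and Schwann cells, and erythroid cells. A lack of calls does not show equal levels, least of all where libraries of a group vary widely. The SD of the mean log2 CPM of slow fibre genes was 1.26 in wild type and 0.66 in the transgenic group. In the same order it was 1.11 and 1.35 for tendon, 0.93 and 0.83 for adipocyte and 0.085 and 0.14 for endothelial markers. Of the 283 different genes tested in the lists with no member past the threshold, 21 had an unadjusted p under 0.05 in edgeR and DESeq2 called 6. Adjusted over the list alone, 3 genes rose in the satellite cell list, 2 among muscle-secreted factors and 1 among tendon markers, and for the other lists fixed in advance and not given above the count was that over all genes tested. Over the 31 lists that did not pass, camera adjusted p values ran from 0.0973 for the proteasome to 0.930 for mitochondrially encoded genes. The proteasome list passed as lower without wild-type library 1, 3 or 4 or transgenic library 3 (camera adjusted p = 0.0245, 0.0234, 0.0401 and 0.00304), and pyruvate dehydrogenase and the TCA cycle without wild-type library 2 (0.00963) or transgenic library 3 (0.00304). Atrophy and autophagy passed as lower without wild-type library 4 (0.0401), and slow fibre as higher without wild-type library 1 (0.0254). With an estimated correlation none of these calls was made, with adjusted p from 0.934 to 0.995. In lists with no member called, 1 gene of beta-oxidation and 1 cytosolic ribosomal protein gene fell without transgenic library 3, and 1 gene rose among ribosomal proteins without transgenic library 5, among muscle-secreted factors without transgenic library 1 or 2 and among tendon markers without transgenic library 2.

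**Figure D3:**
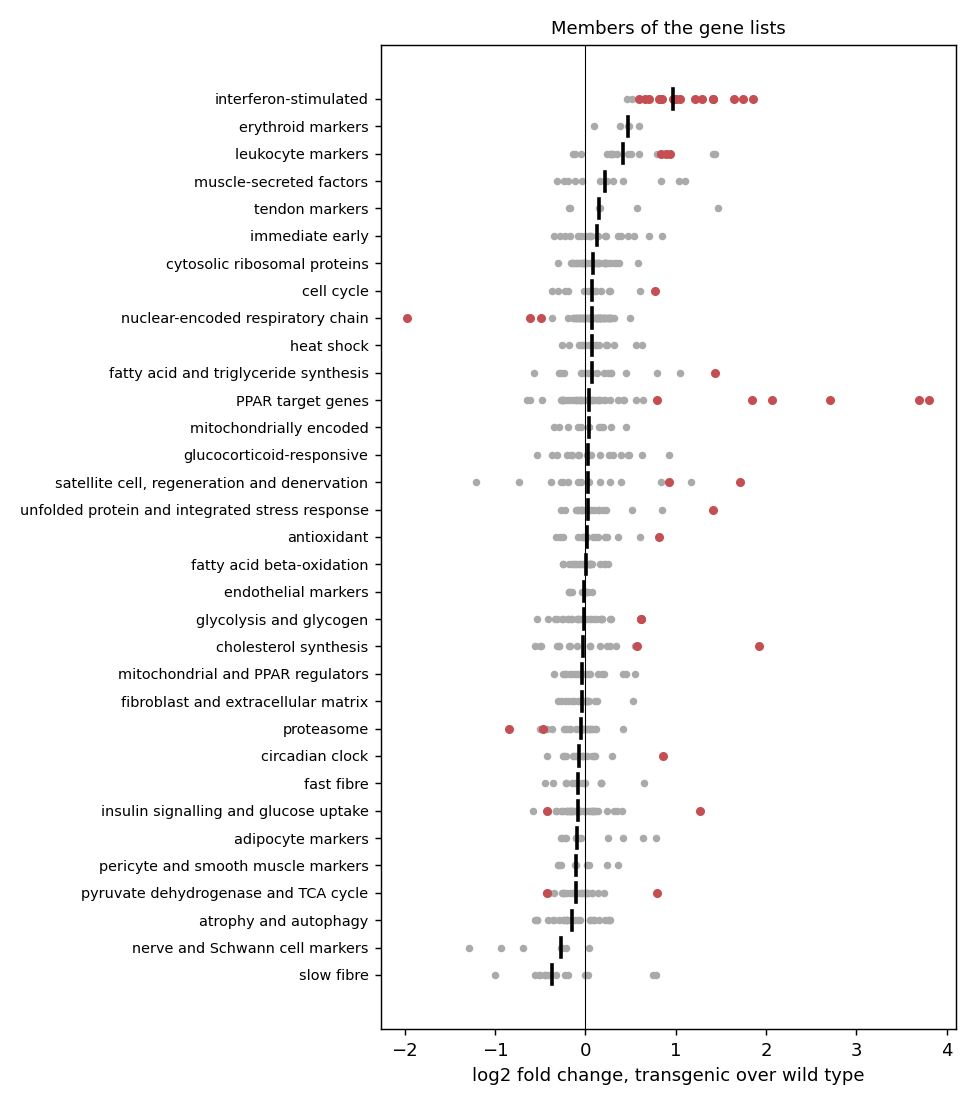
Log2 fold change, transgenic over wild type (horizontal axis), of each tested member of the 33 gene lists; red points passed an edgeR adjusted p of 0.05, grey points did not, and the black bar is the list median. The interferon-stimulated list has the highest median, 0.97.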

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

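The tests on liver transcripts, PPAR target genes and libraries left out for interferon genes were chosen after the result was seen; the splits of all genes and lists were planned, and the split test of the interferon list was added after its rise was seen.

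Of 268 sets of 5 libraries, 21 had a library far from the other 4 by Dixon's criterion, and chance gives 13.4. Transgenic library 3 stood apart most often. Its log2 CPM was 8.56 for Slc2a4, against 7.69 to 7.89 in the other transgenic libraries, 5.85 for Irs1, 7.99 for Pdha1, 7.70 for mt-Nd6, 4.64 for Gabpa, 6.08 for Psma6 and 4.28 for Thrsp. Its mean log2 CPM was 11.9 for fast fibre genes and 3.31 for muscle-secreted factors. In wild-type library 5 the nerve and Schwann cell list was at 3.84, the cholesterol synthesis list at 2.48 and Cdkn1c at 4.62. In transgenic library 5 the cholesterol synthesis list was at 2.42 and the interferon-stimulated list at 3.07. Slc16a1 was at 5.21 in wild-type library 1, Lox at 4.31 in wild-type library 4 and Pax7 at 1.81 in transgenic library 1. The atrophy and autophagy list was at 5.74 in transgenic library 2, and in wild-type library 2 the antioxidant list was at 5.45 and the proteasome list at 6.47. Mitochondrial ribosomal RNA took 11.4% of the counts in wild-type library 4.

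Chance is unlikely for the number of called genes: 1 of 100 splits of the libraries, the real one, gave as many as 711, and the highest other split gave 21. Of 126 possible splits 100 were run. Such splits do not tell the genotype from other differences that follow the groups, the liver transcripts among them. Chance cannot be excluded for the number of lists: 100 of 100 splits called at least 2 lists. The other splits called from 3 to 19, so the real one called the fewest. With the preset correlation lists thus passed in each split run, and passing alone does not set the real groups apart. For the size of the interferon list's median log2 fold change, 1 of 100 splits, the real one, reached 0.97, and the highest other split gave 0.76. The mean log2 CPM of this list was 2.62 to 3.07 in transgenic and 1.53 to 1.97 in wild-type libraries. With groups apart in this way the real split was nearly bound to rank first. The split test thus adds little beyond that separation, which had been seen before it was run.

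Liver transcripts were higher in each transgenic library than in each wild-type library. The log2 ratio of each hepatocyte marker to the mean of the others was taken. Its median SD was 0.151 of the SD of the marker mean within the transgenic libraries, 0.664 within wild type and 0.190 over all libraries. The wild-type value rests on a smaller SD of the mean, 0.450 against 1.46, as the median SD of the ratio was 0.299 against 0.221. The markers thus moved together within the transgenic libraries. Within wild type, where their mean varied less, moving together was not shown. Values that move together do not name their origin, so liver RNA or liver reads from 1 source cannot be told apart from other origins. Within the wild-type libraries 35 of the 41 markers had more than 3 counts in each library and 19 at least 1 CPM, and Cyp2e1 alone gave 37.0% of the markers' wild-type CPM. These counts argue against the transgene as the only origin of the transcripts, unless reads passed between libraries, which was not tested. What raised them in the transgenic group stays open, and a change of expression in muscle by the transgene was not tested.

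PPAR target genes that rose are also expressed by liver, and values for 5 of them are given here; without transgenic library 5 the group difference was 9.77 CPM in place of 26.0 for Cyp4a10, 17.8 in place of 53.0 for Cyp4a14, 1.06 in place of 2.91 for Acaa1b and 9.12 in place of 19.5 for Ehhadh. Beside a term for the hepatocyte markers, the share of the group difference in CPM left was -0.0240 for Cyp4a10 and -0.0388 for Acaa1b. Liver transcripts as the whole cause would give this, but so would any other cause that raised these genes and the markers together. The summed markers ran from 217 to 343 CPM in wild type and from 700 to 7902 CPM in transgenic libraries. The test thus cannot single out liver transcripts. The share was 0.927 for Plin2 and 1.41 without transgenic library 5, both beyond 2 standard errors. This argues against liver transcripts as the whole cause for Plin2. For Cyp4a14 (-0.0863) and Ehhadh (0.146) the cause cannot be told apart: the first was over-corrected beyond 2 standard errors, and for the second the share rose to 0.812 without transgenic library 5. Leaving Cyp2e1 out of the markers gave shares of -0.0219, -0.0344, 0.932, -0.0839 and 0.150 for the genes in the same order.

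The interferon-stimulated list kept a median log2 fold change of 1.03 without transgenic libraries 1 and 2, which hold the most Ptprc, and of 0.72 without transgenic libraries 4 and 5, which hold the most liver transcripts, against 0.97 with all. Its camera adjusted p was 1.01e-15 and 1.05e-15 with a preset correlation, and 0.405 and 0.162 with an estimated correlation. These values argue against leukocytes in the first pair or liver transcripts in the second pair as the whole cause. Liver transcripts were higher in all 5 transgenic libraries, so a part in all of them stays open, as does an effect of the transgene.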

How the results depend on the processing

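The settings on hepatocyte markers, left-out pairs of libraries, prior counts, rows that resemble ribosomal RNA and gene types were chosen after seeing the data. Zfp407 kept its direction and its call in each alternative run, with 4.25 without transgenic libraries 4 and 5 as the lowest log2 fold change and 4.54 as the highest. The count of called genes (711, 571 higher and 140 lower) was 1230 (899 and 331) with DESeq2, 1204 (901 and 303) from the authors' deposited p-values adjusted over the rows used here, and 1133 from those with a mean of at least 10, 312 of them lower. It was 252 (207 and 45) at an adjusted p under 0.01 and 1115 at 0.1, 307 of them lower; with a fold of at least 1.5, 79 were lower. With the hepatocyte markers as a covariate it was 79 (73 and 6); that covariate separates the groups, so it also takes up differences between them. Without transgenic libraries 4 and 5, 56 were lower. DESeq2 kept 704 of the 711 calls. With 1 library left out the count ran from 450 (without wild-type library 3) to 1116 (without transgenic library 3), the higher from 342 to 764 and the lower from 92 (without wild-type library 5 or transgenic library 4) to 352, and the Zfp407 log2 fold change from 4.32 to 4.54; fewer libraries explain part of a lower count, and the cause of the rise without transgenic library 3 was not tested.

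The number of lists past the threshold (2) was 7 with the covariate, 1 without transgenic libraries 1 and 2, 1 at a correlation of 0.05 and 0 with an estimated correlation, where the interferon list alone was under an unadjusted p of 0.05, at p = 0.00297; with 1 library left out it ran from 1 to 4, with 4 without wild-type library 1 or transgenic library 3 and 1 without wild-type library 5 or transgenic library 1 or 2. With the covariate the fibroblast and extracellular matrix list turned to higher, at 4.41 on the negative log10 scale of its p (adjusted p = 0.647 with an estimated correlation). Cytosolic ribosomal proteins, tendon and erythroid markers then passed as higher (camera adjusted p = 1.84e-11, 0.00768 and 0.00575). Mitochondrially encoded genes passed as lower (camera adjusted p = 0.000418). With an estimated correlation the camera adjusted p of these 4 lists ran from 0.647 to 0.691. Cyp4a14 turned to a log2 fold change of -0.15 with the covariate. The cause of these changes was not tested. In 7 lists the median, the mean and the test differ in sign, slow fibre among them. Of 47 named genes called beside Zfp407, 34 lost their call with the covariate, 10 and 14 without the 2 pairs of libraries, and 3 to 12 with 1 library left out. For named genes past the threshold neither as reported nor in the alternative, 29 changes of sign occurred. The proteasome list passed with no filter (camera adjusted p = 0.0492) and cytosolic ribosomal proteins without transgenic libraries 4 and 5 (0.00142), with adjusted p = 0.985 and 0.9998 with an estimated correlation. Nerve and Schwann cell markers passed with log2 fold changes as the ranking (0.0445), where no correlation is estimated. No paired analysis was possible because the columns carry no mouse number, and the planned block by runs of sample numbers was not run for that reason. With a prior count of 0.5 or 8 for log2 CPM in place of 2, the number of lists stayed at 2. In a further simulation at 1, 0.25 and 4 times the depth, edgeR recovered 20%, 22% and 32% of 1.5-fold changes and 98%, 82% and 100% of 4-fold changes.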

Other observations

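Genes in this part were chosen after their values were seen. Beyond the named sets, Gpr27, an orphan receptor, rose from 0.667 ± 0.252 CPM to 9.66 ± 1.55 CPM, Slc2a3, which encodes the glucose transporter GLUT3, from 3.61 ± 1.01 CPM to 25.0 ± 8.04 CPM, and Hs6st2 from 5.78 ± 0.479 CPM to 22.1 ± 3.78 CPM (SD, n = 5 each). Igf2, an imprinted growth factor gene, rose by a log2 fold change of 1.35 ± 0.14 (SE) while the imprinted Cdkn1c fell; Igf2 overlaps Igf2os, and the strand of the reads is not known. Of 16 imprinted genes tested these 2 alone passed, 2 rose and 1 fell when adjusted over the list alone, and the camera adjusted p was 0.255, with 0.0374 without wild-type library 5 and 0.0294 without transgenic libraries 1 and 2. With an estimated correlation the adjusted p was 0.501, 0.178 and 0.181 in the same order, and without transgenic library 5, 2 imprinted genes rose. The imprinted list too was written after called genes had been seen, so its camera p-values describe it and do not test it. Eda rose by 1.84 ± 0.19 and its receptor gene Eda2r fell, at -1.09 ± 0.15 (SE). Cox15, at -1.16 ± 0.10, and Apool, at -1.17 ± 0.14 (SE), encode mitochondrial proteins and fell. With the hepatocyte markers as a covariate Cdkn1c, Eda2r and Apool did not pass (edgeR adjusted p = 0.270, 0.0623 and 0.0765). There Cdkn1c had a log2 fold change of -0.99 ± 0.36, Eda2r one of -1.18 ± 0.26 and Apool one of -1.06 ± 0.25 (SE). Eda2r and Apool thus stayed near their values above with a larger SE, while Cdkn1c shrank from -1.42. The other genes named here passed.

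Of 21 antigen presentation genes, 15 rose and none fell, and 20 rose when adjusted over the list alone, with a median log2 fold change of 0.84. The list was written after called genes had been seen, so its camera p-values describe it and do not test it. With an estimated correlation its unadjusted camera p was 0.0119, against 0.00297 for the interferon-stimulated list. Adjusted p-values of these lists cannot be compared, as the interferon list was adjusted over the larger set of lists fixed in advance. The camera adjusted p over the 3 added lists was 1.19e-16 with a preset correlation and adjusted p = 0.0356 with an estimated correlation. The latter was 0.0518 without wild-type library 5, 0.0623, 0.0603 and 0.0892 without transgenic library 1, 2 and 3, 0.0774 without transgenic libraries 1 and 2 and 0.171 with the hepatocyte markers as a covariate, where 4 members rose. The members that rose were 9, 8, 7 and 7 without wild-type library 2, 3, 4 and 5 and 9 without transgenic library 1 or 2. Without transgenic libraries 1 and 2 together, 6 members passed, H2-Q4, H2-Q6, H2-Q7, Nlrc5, Psmb10 and Tap1. Igkc, an immunoglobulin gene, stood at 15.02 and 10.7 CPM in transgenic libraries 1 and 2, against at most 1.34 CPM in the other libraries.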
